A study of Mus musculus with 42 samples.

How the data were processed

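RRBS was run on sperm of exposed and control males, and RRBS and RNA sequencing on embryonic and extra-embryonic tissue of their E7.5 offspring, per the labels. The deposited data were 1 expression table of 6 libraries and 1 methylation table of 9 libraries. The treatment of each column was taken from its name, and its tissue was left open because neither the names nor the labels give it. The plan written before the data were examined assumed a table per tissue. All planned results on sperm, on the second tissue of each assay, on tissue differences and on the overlap of sperm with embryo were left out for that reason.

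The expression values are CPM (counts scaled to a fixed total) made by the authors, per the file headers, and the table also holds 3 lines without a gene (reads with no unique alignment, outside genes, or in more than 1 gene). The CPM of each library are whole multiples of 1 step within a tolerance of 0.01 for 100% of values, but the deposited columns sum to between 982921 and 1017434, so the totals were scaled by a factor that is not given. The totals are therefore reported as relative depth and not as read counts, and no count model was fitted. The methylation values are percent methylation of 100 bp tiles as deposited by the authors, with no coverage, so no coverage minimum could be applied and no interval for single tiles can be given. Trim Galore, Bowtie2, Bismark, methylKit, Bowtie 0.12.2, TopHat, SAMtools and edgeR are named, with no role or order, per the submitters' processing notes. The builds named there are mm8 and mm10, without saying which table used which.

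Gene coordinates are those of the expression table. To find the build of the tiles, gene ends of the GRCm38.p6 annotation were set against them. Within 500 bp of gene ends lay 43297 tiles with a mean methylation of 9.67%, and within 500 bp of ends shifted by 100000 to 3000000 bp lay 3057 to 5027 tiles with means of 32.9 to 37.7%, so GRCm38 names were used. Tiles were assigned to a gene when they lay within its span or 2 kb on either side (85.1% of tiles, 21926 genes).

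Expression was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(CPM + 1). Genes with at least 1 CPM in 2 or more libraries were kept (12987 of 12988), and the 3 groups stood in 1 fit with 3 residual degrees of freedom. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The plan held a count test and a test for normalized values, and the latter was used because the table holds CPM. The planned Fisher tests on overlapping calls could not be run, because at most 1 gene and no tile was called per comparison. Methylation was tested with limma without a trend on percent methylation, in 1 fit of 9 libraries. Library means were compared with exact permutation tests.

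Gene lists were fixed before the data were examined: cell types of the gastrulating embryo and of the decidua, signalling, Hox, imprinted, germline, metabolic, stress, cell cycle, chromatin, matrix and sex label genes. Of 29 lists, 28 had at least 5 measured genes. Each was tested with camera at a preset correlation of 0.01, adjusted over 84 tests, then again with an estimated correlation, under which 0 lists passed (lowest adjusted p 0.578), and with fry, under which 0 passed (lowest 0.29). With the preset, 10 lists passed for low against control (8 higher, 2 lower), 15 for high against control (11 and 4) and 10 for high against low (7 and 3). Median, mean and test differed in sign in 6, 6 and 9 lists, among them 1 list that passed, that of the primitive streak for high against low. Lists of tiles were compared by their median difference with 10000 random sets of as many genes, adjusted over 81 tests for 27 lists.

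Genes were named by a rule fixed beforehand. Where genes pass, it takes up to 12 per direction whose libraries do not overlap, where none pass the 3 with the smallest p per direction, and beside these up to 4 members of each list with the smallest p. For tiles it takes the 3 with the smallest p per direction where none pass. Predicted genes were to be named only where they are the only ones, which held for Gm23935. Members named because they passed adjusted over a list alone, list tiles, Lars2 and Mir6236 were chosen after their values were seen. The adjustment over a list alone was made within each list and comparison. It was not corrected across lists or comparisons, so some members may pass by chance.

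Limma and camera were first tested on simulated data for high against control, and the other tests were not. For high against control in the expression table, limma recovered 49.7% of genes changed by 1.41-fold, 93.9% at 2-fold and 99.5% at 4-fold. On average 4.43% of its calls were unchanged genes. In each simulation 50 genes were changed at each size together, which eases the adjusted threshold, and no library was an outlier. These shares may therefore be too high for a table with few changed genes. In the real data Gm23935, 2.74-fold higher in low than in control, had adjusted p = 0.254 by limma. Camera with the preset correlation called a list shifted by 0.1 in 20 of 20 simulations with 1 other call, and with the estimated correlation in 2 of 20. Genes were simulated as independent, so this cannot show whether the preset holds for correlated lists. Estimated correlations of the real lists ranged from -0.021 for signalling readouts to 0.898 for Hox genes, with 0.282 for oxidative phosphorylation. The preset p-values of lists above 0.01 may therefore be too small. The first version of the expression simulation failed its criterion, with more unchanged genes called than its fixed limit. Its variances were then drawn from the fitted prior, and the criterion was changed as well, to a mean share of unchanged genes among calls over 20 simulations. For high against control in the methylation table, limma recovered 0.9%, 11.4% and 31.25% of tiles changed by 10, 20 and 30 points. Of 959 calls, 88 were unchanged tiles, which is above the nominal 5%. Only tiles of intermediate mean methylation were changed, so recovery in tiles with little or nearly full methylation was not tested.

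Shared controls were simulated 50 times with unchanged groups, and 50 times with each library left out. For methylation, all libraries and tiles were drawn independently, controls included. Shifts of a whole library and tiles that vary together are therefore left out. Alternatives were another normalization, pseudocount, filter and test, the groups sharing a fit, thresholds, the logit scale, tiles of intermediate methylation, other gene assignments, and leaving out each library. In the expression table, leaving out a library leaves a single library in its group. Gene and list counts from such fits show instability and are not replicated results. Without low 2, the difference between low 1 and low 2 also drops out of the spread. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for gene lists of tiles and permutations.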

Results

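Male C57BL/6J mice were given vehicle, 2.5 or 25 mg/kg/day of DEHP, a phthalate that softens plastics, for 67 days and then mated with females that received none. The study asked whether exposure of the father before conception is seen in the DNA methylation of his sperm and in the methylation and gene expression of his offspring at E7.5, the stage of gastrulation. The labels list 42 samples: 12 sperm samples and 18 embryonic or extra-embryonic samples measured by reduced representation bisulfite sequencing (RRBS, which reads methylation in CpG-rich fragments), and 12 embryonic or extra-embryonic samples measured by RNA sequencing. The deposited tables hold 15 of these samples. The expression table has 6 libraries (2 control, 2 low, 2 high) and the methylation table has 9 (3 per group). Column names give the treatment and a number but no tissue, so the tissue of either table is not known from the labels. Sperm against embryo, embryonic against extra-embryonic tissue and the second tissue of each assay were not analysed here. Read depth is stated for neither table. The CPM values of each library are whole multiples of 1 step, and the totals expressed in those steps were 189 and 188 (in units of 1e6 steps) in the controls, 186 and 194 in the low group, and 154 and 164 in the high group. No coverage stands beside the methylation percentages, so the precision of a single tile is unknown.

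In the offspring of low-dose fathers, Aldh1a2 and Crabp2 lay below both controls in both libraries and Mesp1 and Sp5 above them, but no single gene passed the test over all genes. Such a lack of overlap is common: 35.2% of all genes tested had it for low against control, where chance gives 33.3%. Aldh1a2, the enzyme that makes retinoic acid in the early embryo, was at 1.36 and 10.3 CPM in the low libraries and at 35.3 and 25.8 CPM in the controls (log2 fold change -2.60, SE 0.60, adjusted p = 0.928 by limma). Its log2 fold change was -1.467 without low 1 and -3.723 without low 2. Crabp2, a carrier of retinoic acid into the nucleus, was at 7.07 and 15.4 CPM against 25.3 and 19.3 CPM. Cyp26a1, which degrades retinoic acid, was at 102 and 69.2 CPM against 72.5 and 74.8 CPM. Mesp1, which marks nascent cardiac mesoderm in the primitive streak, was at 58.8 and 50.7 CPM against 31.1 and 33.2 CPM (log2 fold change 0.75, SE 0.08, adjusted p = 0.254). Sp5, a direct target of Wnt signalling in the streak, was at 67.2 and 66.6 CPM against 51.2 and 46.9 CPM. Library low 1 lay farther from the controls than low 2 for Aldh1a2, Crabp2 and Mesp1.

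All 7 measured Hox genes had a negative log2 fold change in the low group, with a median of -0.67. The list was lower than the other genes in a camera test with the preset correlation of 0.01 (adjusted p = 1.73e-04), and the adjusted p was 0.608 with an estimated correlation. Without low 1 the preset call was lost (adjusted p = 0.0733), and the list mean of low 2 (2.325) lay between those of the controls (2.655 and 2.317). Of the 7 Hox genes, 0 passed limma over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 and all of them lower. The adjustment over a list alone, here and below, is not corrected across lists or comparisons. Without low 2 the count over the list alone was 6. Of 28 genes of the primitive streak and mesoderm, 14 were higher and 14 lower (list adjusted p = 0.501), and 5 passed adjusted over the list alone: Mesp1, Sp5, Fgf3, Mesp2 and Fst. The first 4 were higher, and Fst, which encodes an activin antagonist, was lower at 82.4 and 83.3 CPM against 106 and 95 CPM. The count of 5 was 2 without low 1 or either high library and 18 without low 2. Of 23 genes of nuclear receptors and steroid signalling, 2 passed adjusted over the list alone and were lower, among them Aldh1a2 (list adjusted p = 0.101). That count of 2 was 7 without low 2, 1 without low 1, and 0 without any 1 of the other libraries or with a pseudocount of 0.1. Of 37 readouts of Wnt, BMP, Nodal and FGF signalling, Sp5 and Lefty2 passed adjusted over the list alone. Lefty2, a Nodal target that restrains Nodal, was higher at 130.5 and 113 CPM against 89.2 and 87.2 CPM. The count of 2 readouts was 11 without low 2, 1 without control 1 and 0 without control 2 or low 1.

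Genes of oxidative phosphorylation and of the ribosome were slightly higher in the low group. Of 70 genes of oxidative phosphorylation, 65 had a positive log2 fold change, with a median of 0.07, and Cox5a, a subunit of cytochrome c oxidase, was at 123 and 119 CPM against 100 and 103 CPM. The list passed the preset test (adjusted p = 2.82e-11), with adjusted p = 0.608 with an estimated correlation. Of 78 ribosomal protein genes, 75 were higher by a median of 0.07 (adjusted p = 2.2e-09, and adjusted p = 0.62 with an estimated correlation). The unfolded protein response (adjusted p = 7.44e-07) and the oxidative stress response (adjusted p = 3.64e-04) were higher too, each with adjusted p = 0.578 with an estimated correlation. Manf, a secreted protein of the stressed endoplasmic reticulum, was at 105.5 and 110.1 CPM against 91.2 and 89.2 CPM.

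Immediate early and heat shock genes (adjusted p = 8.71e-04, with adjusted p = 0.578 with an estimated correlation) were higher in the low group. Jund, a subunit of the AP-1 transcription factor, was the 1 member that passed adjusted over the list alone, a count that was 4 without control 2, 2 without low 2, and 0 without any other library or after quantile normalization. Cebpb passed adjusted over the decidua list alone (list adjusted p = 0.936), but only with both controls, low 2 and both high libraries in the fit. Targets of p53 (adjusted p = 9.57e-04) were higher, with adjusted p = 0.62 with an estimated correlation, and so were PPAR targets and fatty acid oxidation (adjusted p = 0.00197), with adjusted p = 0.608 with an estimated correlation. Without control 1 the immediate early call ended at adjusted p = 0.101 and the p53 call at 0.407, and without control 2 the PPAR call ended at 0.654. Trophoblast genes were higher (adjusted p = 0.0122, with adjusted p = 0.62 with an estimated correlation), and that call was lost without control 2 (adjusted p = 0.689) or low 1 (adjusted p = 0.413). Extracellular matrix genes were lower (adjusted p = 0.0182, with adjusted p = 0.608 with an estimated correlation), and that call was lost without control 1 (adjusted p = 0.664), in which Lama1, a basement membrane laminin, was at 230.7 CPM against 49.0 CPM in control 2.

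Over the 12987 genes tested, limma called 0 genes between low and control, and 633 had an unadjusted p under 0.05, 247 higher and 386 lower. Leaving out a low or control library leaves a single library in its group, whose own spread is then not measured. Counts from such fits, as without low 2 where low 1 stands alone, are not replicated differences. Leaving aside the predicted gene Gm23935 (2.74-fold higher, adjusted p = 0.254 by limma), the genes with the smallest p were Mesp1, Scand1 and Nr2f6 among higher genes and Gli2, Ror1 and Bcan among lower genes. Gli2, a transcription factor of Hedgehog signalling, was at 28.4 and 29.9 CPM against 42.7 and 39.2 CPM, and Ror1, a Wnt5a receptor, at 20.8 and 24.4 CPM against 35.4 and 32 CPM.

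**Figure D1:**
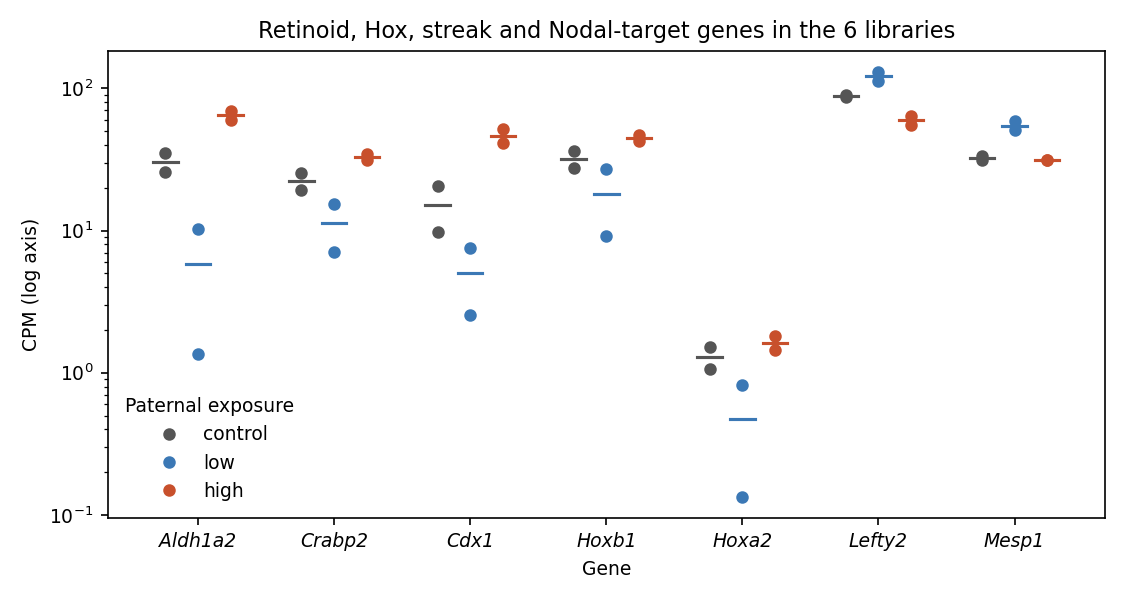
CPM (log axis) of 7 genes in the 6 expression libraries; points are libraries and short lines are the means of the 2 libraries of a group. Aldh1a2 lay at 1.36 and 10.3 CPM in the low group, 35.3 and 25.8 CPM in the controls, and 59.7 and 69.6 CPM in the high group, while Lefty2 and Mesp1 were highest in the low group.

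In the offspring of high-dose fathers, 1 gene passed the test: Gm23935 (ENSMUSG00000076258, chromosome 16, 11144125 to 11144181, coordinates of the expression table), a predicted gene with no assigned function. It was at 192 and 195 CPM in the high libraries and at 56.6 and 36.6 CPM in the controls (4.19-fold, log2 fold change 2.07, SE 0.17, adjusted p = 0.0438 by limma), and at 128 and 125 CPM in the low libraries. The call was lost without either high library, with limma without a trend (adjusted p = 0.273) and with the column number as a replicate block. The log2 fold change stayed at 2.077 without high 1 and 2.055 without high 2. Without either low library the count of called genes was 2. In all, 687 genes had an unadjusted p under 0.05, 474 of them higher and 213 lower.

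The lists with the smallest p-values in the high group were those of the visceral and parietal endoderm, the epithelia that feed the embryo, and of the respiratory chain. Of 33 endoderm genes, 30 were higher, with a median log2 fold change of 0.44 (adjusted p = 6.57e-09, and adjusted p = 0.62 with an estimated correlation). Apoa1 and Apoc2, lipoprotein components, were at 234 and 299 CPM and at 90.5 and 115.7 CPM, against 212 and 124 CPM and 74.9 and 38.4 CPM in the controls. Without control 2, in which these genes were lowest, the endoderm call was lost (adjusted p = 0.271) and the median was 0.11, with the test turning lower. The list mean of control 1 (6.258) lay between those of the high libraries (6.133 and 6.368), so the difference rested on control 2. All 15 measured genes of the extraembryonic mesoderm were higher, with a median of 0.41 (adjusted p = 2.26e-04, and adjusted p = 0.62 with an estimated correlation), a call lost without high 2 (adjusted p = 0.375). Of 70 genes of oxidative phosphorylation, 66 were higher with a median of 0.08 (adjusted p = 6.33e-08, and adjusted p = 0.608 with an estimated correlation), and Cox5a passed adjusted over the list alone with all 6 libraries in the fit and not without any 1 of them, which left a count of 0. Ribosomal protein genes were higher in 69 of 78 cases (adjusted p = 1.57e-05, and adjusted p = 0.689 with an estimated correlation), and the call was lost without control 1 (adjusted p = 0.215) or high 1 (adjusted p = 0.721).

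The Hox genes, which pattern the body axis, were higher in the high group as a list. All 7 measured Hox genes were higher, with a median of 0.50 (adjusted p = 0.00197, and adjusted p = 0.62 with an estimated correlation), and 0 passed adjusted over the list alone, a count that was 6 without either low library and 1 without control 1 or after quantile normalization. Rarb, a retinoic acid receptor induced by its own ligand, was at 4.05 and 3.85 CPM against 2.29 and 1.56 CPM, and Esrrb, a nuclear receptor of pluripotent and trophoblast cells, was at 7.02 and 5.77 CPM against 1.06 and 1.07 CPM. Both passed adjusted over the 23 genes of their list alone, and the list itself did not pass (adjusted p = 0.0567). The count of 2 was 0 without control 2 or either high library, 5 without either low library and 1 with a pseudocount of 0.1. Cdx1, a caudal patterning gene, was at 51.7 and 41.2 CPM against 20.6 and 9.72 CPM (log2 fold change 1.63, SE 0.43, adjusted p = 0.866). Lefty2 and Cer1, secreted Nodal antagonists, were lower and passed adjusted over the list of signalling readouts alone. Lefty2 was at 64.1 and 54.9 CPM against 89.2 and 87.2 CPM, and Cer1 at 87.6 and 80 CPM against 115 and 140 CPM. That count of 2 was 0 without control 2 or high 2, 1 without high 1, 5 without control 1 and 14 without either low library. Fst passed adjusted over the streak list alone (list adjusted p = 0.187), where the count was 0 without either high library, 3 without control 1 and 9 without either low library.

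Stress, decidua, imprinted and trophoblast genes were among the other lists that passed in the high group. The oxidative stress response (adjusted p = 8.4e-04) and the maternal decidua list (adjusted p = 8.71e-04) were higher, each with adjusted p = 0.578 with an estimated correlation. Hand2 and Cebpb, transcription factors of the decidua that embryonic cells can also express, passed adjusted over the decidua list alone, and Hand2 was at 6.61 and 7.95 CPM against 4.34 and 3.75 CPM. That count of 2 was 0 without either high library, 1 without control 2 and 3 without either low library. The unfolded protein response (adjusted p = 8.71e-04, lost without control 1 at 0.0929) and PPAR targets (adjusted p = 8.4e-04, lost without control 2 at 0.174) were higher, each with adjusted p = 0.608 with an estimated correlation. Imprinted genes (adjusted p = 0.0104) and trophoblast genes (adjusted p = 0.019) were higher, each with adjusted p = 0.62 with an estimated correlation. Esrrb and Sox21 passed adjusted over the trophoblast list alone, a count of 2 that was 0 without control 2 or high 2, 1 without high 1 and 9 without either low library. Definitive endoderm (adjusted p = 0.015), epiblast (adjusted p = 0.0103) and sex label genes (adjusted p = 0.0394) were lower, each with adjusted p = 0.608 with an estimated correlation, as were chromatin enzymes (adjusted p = 0.00589, and adjusted p = 0.62 with an estimated correlation). Cer1 passed adjusted over the definitive endoderm list alone, where the count was 0 without control 2 or high 2, 4 without control 1 or high 1 and 2 without either low library. Imprinted, trophoblast, epiblast, chromatin and sex label calls were lost without control 2 (adjusted p of 0.188, 0.683, 0.151, 0.201 and 0.683) and without high 2 (0.762, 0.302, 0.235, 0.0542 and 0.492). The definitive endoderm call was lost without control 1 (adjusted p = 0.127) or high 2 (adjusted p = 0.375). After quantile normalization the definitive endoderm and sex label calls were lost too (adjusted p of 0.0643 and 0.096).

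Set directly against each other, the high libraries held more RNA of Aldh1a2 and Cdx1 and less of Lefty2 and Mesp1 than the low libraries, and no single gene passed the test. Aldh1a2 was 12.7-fold higher in the high group on the log2(CPM + 1) scale (59.7 and 69.6 CPM against 1.36 and 10.3 CPM, log2 fold change 3.66, SE 0.60, adjusted p = 0.233 by limma). Cdx1 was 8.55-fold higher (51.7 and 41.2 CPM against 2.56 and 7.54 CPM). Without low 1 the folds were 5.8 and 5.52, and without low 2 they were 27.7 and 13.2. Lefty2 was lower at 64.1 and 54.9 CPM against 130.5 and 113 CPM (log2 fold change -1.02, SE 0.09, adjusted p = 0.0998), and so was Mesp1 at 31.4 and 31.2 CPM against 58.8 and 50.7 CPM (adjusted p = 0.131). Limma called 0 of 12987 genes, and 1027 had an unadjusted p under 0.05, 739 of them higher and 288 lower. The count was 9 with the high and low groups alone in the fit, where Lefty2, Htra1 and Mesp1 were among those past the threshold (adjusted p of 0.0366, 0.0366 and 0.0451). Fits with a library left out hold a group of a single library, so their counts are not read as replicated differences.

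All 7 measured Hox genes were higher in the high than in the low group and passed adjusted over the list alone, with a median log2 difference of 1.07. The list passed the preset test (adjusted p = 1.02e-08), with adjusted p = 0.608 with an estimated correlation. Of the 23 genes of nuclear receptors and steroid signalling, 7 passed adjusted over the list alone and were higher, among them Crabp2, Aldh1a2, Rarb, Esrrb and Crabp1 (list adjusted p = 0.00197, and adjusted p = 0.608 with an estimated correlation). Part of the median difference of the Hox list came from low 1, without which it was 0.57, and it stood at 1.16 without high 1 and 0.985 without high 2. The Hox count was 0 without high 1 and 2 without high 2, the nuclear receptor count was 0 without either, and the nuclear receptor list call itself was lost without high 1 (adjusted p = 0.0836). Without low 1 the counts were 6 and 5.

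Of 28 genes of the primitive streak and mesoderm, 15 passed adjusted over the list alone, in both directions. Mesp1, Mesp2, Sp5, Fgf3, Wnt3, Lhx1, Eomes and Snai1 were lower in the high group, with Eomes, a T-box factor that specifies mesoderm and endoderm, at 110 and 86.5 CPM against 233 and 137 CPM. Cdx1, Cdx4, Hoxb1, Wnt3a, Hes7, Pdgfra and Msgn1 were higher, with Msgn1, a factor of presomitic mesoderm, at 17.6 and 15.1 CPM against 0.721 and 6.59 CPM. The list's median was -0.20, its mean was 0.13, and the test gave lower (adjusted p = 0.0104, and adjusted p = 0.578 with an estimated correlation). The list call was lost without low 2 (adjusted p = 0.252), without high 2 (adjusted p = 0.139) or after quantile normalization (adjusted p = 0.096), and the count of 15 was 3 without high 1, 2 without high 2, 8 without low 1 and 21 without low 2. Of 21 epiblast and neurectoderm genes, 9 passed adjusted over the list alone, among them Pou5f1, Dnmt3b, Hesx1, Sox3, Utf1, Lin28a, Zic2 and Sox1 (list adjusted p = 0.109). The count of 9 was 1 without high 2, 3 without high 1 or low 1, 16 without either control and 19 without low 2. Sox1, the earliest marker of the neural plate, was at 2.25 and 2.88 CPM against 0.242 and 0.907 CPM. Of 37 signalling readouts, 8 passed adjusted over the list alone: Sp5, Lefty2, Id2, Spry2, Fgfr2, Fgfr1, Cer1 and Fgf4 (list adjusted p = 0.501), a count of 8 that was 1 without high 2, 2 without high 1 or low 1 and 22 without low 2. Shh passed adjusted over the definitive endoderm list alone (list adjusted p = 0.191), at 4.25 and 3.90 CPM against 0.414 and 1.57 CPM, where the count was 0 without high 2, 5 without high 1 or low 2, 6 without either control and 2 after quantile normalization.

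Extraembryonic mesoderm (median 0.55, adjusted p = 6.46e-05) and imprinted genes (median 0.09, adjusted p = 0.00197) were higher in the high than in the low group, each with adjusted p = 0.62 with an estimated correlation. Both calls were lost without low 1 (adjusted p of 0.0984 and 0.0605) and without high 2 (0.196 and 0.328). Smoc1, an imprinted gene of BMP signalling, passed adjusted over the imprinted list alone, at 30.5 and 29.7 CPM against 18.5 and 19.5 CPM. Visceral and parietal endoderm genes were higher (adjusted p = 9.64e-05, and adjusted p = 0.646 with an estimated correlation), a call lost without high 2 (adjusted p = 0.139). The decidua list was higher (adjusted p = 0.00197) and so was the cell cycle list (adjusted p = 0.00648), each with adjusted p = 0.578 with an estimated correlation. The cell cycle call was lost without low 2 (adjusted p = 0.199) or high 1 (adjusted p = 0.0873). Targets of p53 were lower (adjusted p = 0.00197, and adjusted p = 0.62 with an estimated correlation), among them Pmaip1, which encodes the death-promoting protein Noxa, and the call was lost without high 2 (adjusted p = 0.127). Immediate early genes were lower (adjusted p = 0.022, and adjusted p = 0.608 with an estimated correlation), a call lost without low 1 (adjusted p = 0.224), without high 1 (adjusted p = 0.507) or after quantile normalization (adjusted p = 0.0866). Other single genes that passed adjusted over their list alone were Wnt6, Esrrb and Sox21 (trophoblast), Tal1 (blood), Hand2 (decidua), Dnmt3l (DNA methylation machinery), and Vcan and Tnc (extracellular matrix). Without high 2 these counts were 0, with 1 for the matrix list, and so were those of the imprinted and p53 lists. Without low 2 they were 11 for trophoblast, 11 for imprinted, 9 for matrix, 5 for blood, 5 for DNA methylation machinery and 2 for decidua. Without high 1 the trophoblast and matrix counts were 1 and the others 0, and without low 1 the blood, imprinted, p53 and matrix counts were 0. Without either control they were 9 for matrix, 5 for trophoblast, 3 for blood and 2 for DNA methylation machinery. With a pseudocount of 0.1 the count was 1 for trophoblast and 0 for blood and p53, and after quantile normalization it was 0 for DNA methylation machinery.

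**Figure D2:**
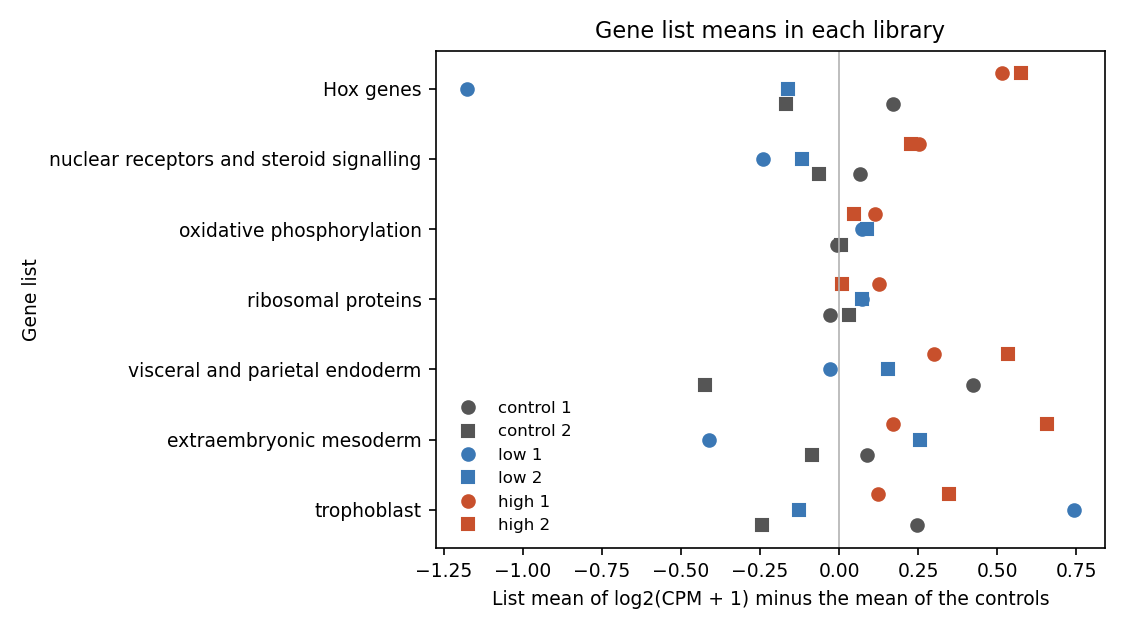
Mean of log2(CPM + 1) over 7 gene lists in each expression library, minus the mean of the controls; circles are libraries numbered 1 and squares libraries numbered 2. The Hox list lay lowest in low 1 and above both controls in both high libraries, while the endoderm list spread widely between the controls themselves.

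Lists of cholesterol and lipid synthesis, glycolysis and germline genes passed in none of the 3 comparisons. In the order low against control, high against control and high against low, the adjusted p-values of the preset test were 0.905, 0.728 and 0.907 for cholesterol and steroid synthesis and 0.919, 0.801 and 0.939 for lipid synthesis. They were 0.322, 0.0874 and 0.513 for glycolysis and hypoxia, 0.392, 0.935 and 0.43 for germline genes, and 0.192, 0.744 and 0.501 for blood and endothelium. They were 0.147, 0.426 and 0.666 for the DNA methylation machinery and 0.939, 0.43 and 0.501 for the signalling readouts. Beside the signalling readouts, Tal1 and Dnmt3l given above, Lmo2, a blood-forming transcription factor, passed adjusted over its list alone for high against control. That count of 1 was 0 without control 2 or either high library, 4 without control 1, and 2 without either low library or after quantile normalization. Genes encoded by the mitochondrial genome were too few in the table for a test.

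Gene differences in low and high offspring were less correlated than in simulated unchanged groups sharing controls, which rested on low 1. They had the same sign as often. Across genes, which are not independent replicates, the log2 fold changes of low and high against the same controls had a Pearson correlation of 0.174, where simulated unchanged groups sharing controls gave 0.501. The Spearman correlation was 0.367 against a simulated 0.468 and the covariance 0.00376 against 0.00672, while 66.8% of genes had the same sign at both doses against a simulated 66.6%. Unchanged groups simulated with 1 library fewer gave 0.671 without control 1 (observed 0.54), 0.666 without control 2 (observed 0.299), 0.408 without low 1 (observed 0.471) and 0.416 without low 2 (observed -0.074). At an unadjusted p under 0.05, 97 genes were higher at both doses (81.2 simulated, 9.02 for independent lists), 28 were lower at both (82.6 simulated, 6.33 independent), and 27 went opposite ways (3.92 simulated with a highest of 10, 18.1 independent). The simulation leaves out real effects and the independent lists leave out the shared controls, and with 2 controls the controls could not be split. The simulated range (highest Pearson correlation 0.533) is too narrow for genes that vary together, as in an outlying library such as low 1. Values outside that range therefore do not by themselves show that the doses differ.

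The methylation table holds 141251 tiles of 100 bp on 21 chromosomes, each with a value in all 9 libraries. Mean methylation was 35.66% ± 0.41 (SD, n = 3) in the controls, 35.98% ± 0.33 (SD, n = 3) in the low group and 35.97% ± 0.08 (SD, n = 3) in the high group. The differences were smaller than the spread of the controls (two-sided exact permutation p = 0.4 for low, 0.3 for high and 0.9 between doses, adjusted p = 0.6, 0.6 and 0.9, where the smallest p this design allows is 0.1). The median over tiles was lower, not higher, in both exposed groups, by 0.37 and 0.28 percentage points. That rested on control 1 (21.71%), as control 2 (20.4%) and control 3 (20.61%) lay within the range of the exposed libraries (20.21 to 20.77%).

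Cadps2, Naa16 and Rnf216 held tiles with the smallest p-values, though no tile passed limma in any comparison. A tile in Cadps2, a gene of vesicle release (chromosome 6, 23839901 to 23840000), was at 4.45% ± 0.51 (SD, n = 3) in the low group and 3.73% ± 1.73 (SD, n = 3) in the high group against 16.3% ± 0.39 (SD, n = 3) in the controls (adjusted p = 0.183 and 0.19 by limma). A tile in Naa16, an auxiliary subunit of an N-terminal acetyltransferase (chromosome 14, 79390401 to 79390500), was at 0.242% in the low group against 10.2% in the controls and 9.77% in the high group (adjusted p = 0.183 and 0.132). A tile in Rnf216, a ubiquitin ligase (chromosome 5, 143112301 to 143112400), was at 9.05% in the high group against 0.249% in the controls and 0.545% in the low group (adjusted p = 0.19 and 0.132). A tile at Car11 and Dbp, a clock output gene (chromosome 7, 45703601 to 45703700), was at 50% in the low group against 36.6% in the controls (adjusted p = 0.183).

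The counts of called tiles were 0, 0 and 0, with 7748, 6270 and 6652 at an unadjusted p under 0.05 for low against control, high against control and high against low (5.49%, 4.44% and 4.71% of tiles). Limma on logit values called 5, 8 and 8, limma with a trend 1, 2 and 2, and without control 2 the first 2 comparisons gave 1 tile each. In simulated high-against-control data from this table, only tiles of intermediate mean methylation were changed. Of these, 11.4% of tiles changed by 20 points and 31.25% of those changed by 30 points were recovered. Differences of that size in single tiles of intermediate methylation would therefore mostly have been missed. Recovery in tiles with little or nearly full methylation was not simulated.

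Methylation gains outnumbered losses in both exposed groups. Of tiles at an unadjusted p under 0.05, 59.4% were higher in the low group and 59.5% in the high group than in the controls, and 50.6% were higher in high than in low. Without control 1, the library with the lowest mean methylation (35.24%), the shares were 52.5% and 53.7%, and without low 3 the low share was 53.6%. Control 1 was not simply less methylated: it had the highest median over tiles (21.71%) and the most tiles at 0% (7.41%, at most 5.96% elsewhere). Among tiles of 10 to 90% mean methylation the shares were 65.4% and 64.3%.

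**Figure D3:**
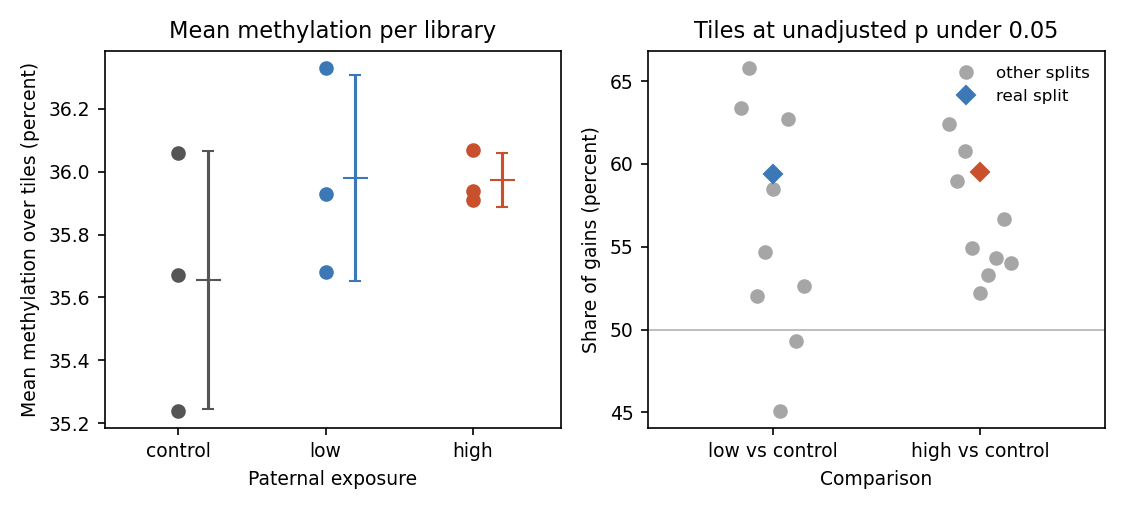
Left, mean methylation over 141251 tiles in each library (points) with the group mean and SD (n = 3); right, the share of tiles at an unadjusted p under 0.05 that were higher in the exposed group, for the real grouping and the other 9 splits of the same 6 libraries. Mean methylation was lowest in control 1 at 35.24%, and other splits reached shares above the real 59.4% and 59.5%.

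Tiles within Hox and germline genes or 2 kb on either side differed from random sets of genes at the low dose. They differed from tiles of matched methylation at neither dose. Tiles at the 39 Hox genes had a median difference of -0.443 points in the low group (adjusted p = 0.0324 against 10000 random sets of genes) and of -0.218 points in the high group (adjusted p = 0.0729). Tiles at 31 germline genes, which are normally methylated in somatic cells, had a median difference of 0.528 points in the low group (adjusted p = 0.0324) and 0.376 points in the high group (adjusted p = 0.0729). With tiles within 1 kb of gene ends both lists passed at both doses (adjusted p = 0.0081 and 0.0297 for Hox, 0.0297 and 0.0081 for germline genes, low and high). In that assignment the definitive endoderm list passed too, at 0.556 points for low against control and -0.496 points for high against low (adjusted p = 0.0243 each). The next checks, matched tiles and left-out libraries, used only tiles in the gene span or 2 kb on either side. The calls near gene ends, definitive endoderm among them, were not checked in these ways. Against random tiles of matched methylation level, neither list passed (adjusted p = 0.31 for Hox and 1.0 for germline in the low group, 0.679 and 1.0 in the high group). Without control 1 the medians in the low group were -0.0168 and 0.119 points, and those in the high group changed sign to 0.124 and -0.114 points. The low-group medians depended on low libraries too, at -0.0085 points for germline genes without low 1 and -0.176 points for Hox without low 2. Imprinted genes had a median of -0.029 points in the low group and 0.077 points in the high group, with adjusted p = 0.905 for each against random sets of genes.

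The single tiles that passed adjusted over their list alone included some in Ndufa10 (82.2% against 90.1%), Ndufs6 (13.9% against 21.2%) and Spred2, a brake on FGF signalling (55.5% against 73.3%), all for low against control. For high against control they lay in the germline genes Slc25a31 (27% against 35.8%) and Asz1 (77.9% against 68.0%), and for high against low in the same Spred2 tile (76.0% against 55.5%). None of these passed over all tiles, with adjusted p between 0.384 and 0.936.

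Tile differences at the doses correlated about as much as simulated unchanged groups sharing controls would, but shared gains were more numerous and shared losses fewer. Across tiles, which are not independent replicates, the correlation was 0.503 against a simulated 0.5, and the covariance 6.9 against 6.85. The Spearman correlation of 0.455 (highest simulated 0.449) and the share of tiles with the same sign of 67.2% (highest simulated 67%) lay above every simulation, and without control 1 the Pearson correlation of 0.574 lay below every one (lowest 0.594). Tiles at an unadjusted p under 0.05 that were higher at both doses numbered 1250 (992 simulated with a highest of 1080, 122 for independent lists), and those lower at both numbered 751 (1030 simulated, 56.5 independent). With 3 controls, the controls could not be split into parts of at least 2, so how much of the excess comes from them is not known. The simulation drew all libraries, controls included, independently around each tile's mean. A correlation near 0.5 and similar numbers of gains and losses are therefore built in, and a shift of a whole library such as control 1 is left out. Its range is too narrow for tiles that vary together, so values outside it do not by themselves show an effect. Those going opposite ways numbered 44 (63.1 simulated, 166 independent).

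Methylation and expression differences were nearly unrelated across genes. Over 11655 genes, the Spearman correlation of the methylation difference with the log2 fold change was -0.034 for low against control (permutation of genes, adjusted p = 9e-04), -0.006 for high against control (adjusted p = 0.487) and -0.013 for high against low (adjusted p = 0.226). With tiles within 1 kb of gene ends the first was -0.001 (adjusted p = 0.933). The tables are not known to come from the same tissue.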

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

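The tests on carried-over cells, depth, several alignments, ribosomal RNA, the left-out control and the tile counts of other splits were chosen after the results were seen, while those on late genes and on the share of gains in other splits were written down before their own values were computed. Groups of 2 or 3 libraries are too small for a test of outlying libraries.

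Reads with no unique alignment, which enter no comparison, made up 22.9 and 22.6% of the listed values in the low libraries, a mean of 22.8%, and 21.9 and 22.2% in the controls, so both low libraries lay above both controls.

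The Hox genes, Aldh1a2 and Crabp2 were lowest in low 1, which was also the library farthest along the main axis of variation (47.1% of variance). Carried-over trophoblast would dilute epiblast genes as well, but their median log2 ratio in low 1 to the other libraries was 0.347 (quartiles -0.258 and 0.6), while that of the Hox list was -1.3. Lower depth is argued against by a total of 186 (in units of 1e6 steps), within the range of the other libraries (154 to 194). A list of late gastrulation and early organ genes, such as Nkx1-2 (14.7 CPM in low 1 and 44.4 to 82.2 CPM elsewhere), Isl1 and Mef2c, was lowest in low 1 in 75% of its 12 measured members, where chance gives 16.7%. That 16.7% holds only for genes that vary independently. Other lists had like shares lowest in low 1, with 86.7% for extraembryonic mesoderm and 72.2% for maternally imprinted genes. Shares over all lists ran from 0% (ribosomal proteins) to 100% (Hox genes), so 75% is not particular to late genes. A pool of slightly younger embryos is a candidate explanation for low 1 that this share does not decide. Whether paternal exposure or the time of collection would cause it stays untested. The high group leaned the other way. All late genes but Myl7 and Cyp26a1 had a higher mean there than in the controls, and 15 of 21 epiblast genes were lower. Stage was not tested in the high group, and it cannot be told apart from dose in either exposed group.

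Gm23935 rose from control to high, and Lars2 (402 and 348 CPM in controls, 510 and 449 in low, 712 and 611 in high) and Mir6236 (3.34 and 2.41, 4.74 and 4.15, 7.56 and 6.48 CPM) had the same order without passing the test. Lower depth is argued against by the low libraries, which had totals like the controls and a fold of 2.74. For the high group, more reads with several alignments are argued against by their share of 21.2%, below both controls. For the low group they are not, as that share was 22.9 and 22.6% against 21.9 and 22.2% in the controls. A share over the whole library also cannot show such reads at a single gene. All 3 measured features that hold ribosomal RNA-like sequence were higher in both high libraries than in both controls, but they were chosen with their values in view, so this count is no test. Library preparation that kept more ribosomal RNA stays open, because no label gives the batch.

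Methylation differences were mostly gains in both exposed groups. Without control 1 the share of gains was 52.5% for low and 53.7% for high, which is consistent with that library carrying part of the imbalance, though without low 3 the low share was 53.6% as well, and control 1 also stood alone on the first principal component (16.2% of variance). Of the 10 splits of the 6 libraries, 4 for low and 3 for high gave a share as far from 50%, with a real departure of 9.4 and 9.54 points and a highest other of 15.8 and 12.4 points. As many tiles at an unadjusted p under 0.05 came from 7 of 10 splits for low against control (7748, highest other 8756), 10 of 10 for high against control (6270, highest other 7073) and 7 of 10 for high against low (6652, highest other 7222). With 10 splits no share under 0.05 is possible, and a difference from the fathers' exposure stays open.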

How the results depend on the processing

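The alternatives with the column number as a replicate block, limma with a trend for tiles, tiles near gene ends, matched tiles, other scalings for lists, left-out libraries for counts over a list alone, for lists of tiles and for the folds of Aldh1a2 and Cdx1, and all alternatives of the overlaps were chosen after the results were seen. Counts of called genes under leave-one-out ranged from 0 to 65 (low against control), 0 to 2 (high against control) and 0 to 291 (high against low), and those of called lists from 10 to 13, 9 to 16 and 7 to 13. The highest gene counts of both comparisons with the low group came without low 2, which leaves low 1 alone in its group, so they are not replicated results. With only the groups compared in the fit, high against control gave 2 genes and high against low 9. Limma without a trend gave 0 for high against control, where Gm23935 stood at adjusted p = 0.273, and an adjusted p under 0.1 gave 1 for high against low. Lists fell to 0, 0 and 0 with an estimated correlation and with fry. Correlations of low and high differences ranged from -0.074 to 0.54 for expression and from 0.439 to 0.62 for methylation, where unchanged groups of the same sizes gave 0.408 to 0.671 and 0.447 to 0.601. For methylation the value lay below every simulation without control 1 (0.574, lowest 0.594) and above every one without control 2 (0.62, highest 0.607), control 3 (0.619, highest 0.608), high 3 (0.469, highest 0.456) or low 2 (0.456, highest 0.455).

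Called tiles were 5, 8 and 8 on the logit scale, 1, 2 and 2 with a trend, and 0 to 1 (both exposed groups) and 0 to 0 (between doses) under leave-one-out. In tiles of 10 to 90%, the counts at unadjusted p were 4678, 3599 and 4029 because fewer tiles were tested, and the gains were 65.4% and 64.3%. Under leave-one-out, gains ranged from 52.5 to 62.5%, 53.7 to 62.3% and 47.5 to 54.5%, the counts at unadjusted p from 7463 to 8549, 6091 to 7511 and 6359 to 7926, and the differences of mean methylation from 0.11 to 0.52, 0.11 to 0.52 and -0.15 to 0.17 points. The median over tiles reversed them to -0.37, -0.28 and 0.1, and the reversals against the controls rested on control 1. Tiles near gene ends gave 3, 2 and 1 called lists, and a methylation and expression correlation of -0.001 for low against control. Apart from these the cause was not tested.

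The column numbers do not pair the libraries: deviations of same-numbered expression libraries correlated at 0.00349, -0.0727 and 0.0896 and those of tiles between -0.0329 and 0.0286, and with the replicate block the expression counts were 0, 0 and 0 and the tile counts 0, 0 and 0. Of 156 values for 13 named gene differences under alternatives, 134 kept direction and side of the threshold, 18 passed newly, 4 no longer passed and 0 reversed. Not run were the coverage minimum, the fit of 12 libraries, promoter tiles, and all sperm and tissue alternatives, for lack of the data.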

Other observations

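The tests on trophoblast, on the tissue of the expression table and on the sex of the pools were chosen after the results were seen, while that on imprinted genes was written down before its value was computed. The rule for reading the relation of Xist to Y-linked genes was made stricter after its value was seen.

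Embryonic and extra-embryonic marker genes were both present in the expression table. Epiblast genes had a median of 48.4 to 76.7 CPM per library, with Dnmt3b, a DNA methyltransferase of the epiblast, at 940 to 1519 CPM, and trophoblast genes had a median of 3.65 to 13.3 CPM. The lowest ratio of these medians was 5.78, in low 1, which argues against extra-embryonic ectoderm as the tissue of the table. In the methylation table, regions near the ends of 16 maternally imprinted genes had a median of 40.8%, and 12 of them lay between 25 and 75%. Sperm lacks methylation at these regions, so the value argues against sperm, and whether the tissue was embryonic or extra-embryonic stays open. Regions near the ends of 21 germline genes had a median of 52.9%, against 5.74% for protein-coding genes in general.

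Low 1 also held the most RNA of several trophoblast genes: Prl3d1, a hormone of giant cells, was at 28.4 CPM (at most 9.72 elsewhere), Plet1 at 43.6 CPM (at most 7.65) and Krt7 at 21.1 CPM (at most 9.42). Of 21 measured trophoblast genes, 52.4% were highest in low 1, where chance gives 16.7%, but so were 52.4% of the epiblast genes, and of the 3 most abundant members Eomes was and Furin and Hand1 were not. Carried-over trophoblast cells may have contributed to low 1, and the values do not decide it. Eomes, Hand1, Cdx2 and Rhox5 are also expressed by the embryo or held by other lists.

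The labels give the embryos as male, yet Xist, the RNA that silences one X chromosome in females, was at 442 to 742 CPM in all 6 libraries, beside the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Over the 6 libraries Xist and the mean of these genes had a Pearson correlation of -0.833 (exact permutation p = 0.0458, adjusted p = 0.0917) and a Spearman correlation of -0.771 (exact permutation p = 0.103). Without high 2 and control 1, the farthest in Xist, the Pearson correlation was 0.281, so the relation rests on those libraries. Xist beside Y-linked RNA (3.54 to 17.8 CPM) in every library argues against libraries of male cells alone. The correlation asks only whether their amounts vary against each other between libraries. Pools of male and female embryos are a candidate explanation, and where the female RNA came from was not tested.

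The expression table opens with 62 lines that break its order of gene identifiers. Of these, 95.2% had an unadjusted p under 0.05 for low against control, where the rest of the table had 4.44%, and 37.1% had it for high against control.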
